A study of Homo sapiens with 3 samples.

How the data were processed

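Small RNA was measured in SK-MEL-2, an established human melanoma cell line. Cells were either left untreated or exposed to a nonthermal plasma jet, a stream of partly ionised gas near room temperature, for 3 or 5 min. RNA was collected on Day 2, per the labels. There was 1 library per group and 3 libraries in all. Per the labels' protocols, total RNA was extracted with Trizol and libraries were built with a NEBNext small-RNA kit. Such kits ligate adapters to both RNA ends and amplify by PCR. Adapter ligation favours some ends over others, so counts of different miRNAs within a library are not molar amounts, while the ratio of 1 miRNA between libraries is less affected.

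The deposited values are whole-number read counts per mature miRNA, and the same 2588 human miRNAs were listed for each library. Per the submitters' processing notes, Bowtie2, bedtools and edgeR were used, with no version and no role given. The genome build, the miRNA annotation, adapter trimming, the treatment of reads that match several miRNAs and the use of strand are not given in the sources used here. These gaps bear on the counts in 3 ways. Mature miRNAs with identical or near-identical sequence (the let-7 members, miR-192-5p and miR-215-5p, miR-29a-3p and miR-29c-3p, the miR-181 members, miR-199a-5p and miR-199b-5p, the miR-320 members) can share reads, so their separate values are uncertain. A miRNA whose hairpin lies antisense to another hairpin (miR-7-5p, miR-24-3p, miR-122-5p, miR-3184-5p) can carry its partner's reads if strand was ignored. An entry that overlaps a ribosomal, small nuclear or transfer RNA can carry fragments of that RNA. The counts hold no molecular identifiers, so PCR copies of 1 molecule count as several reads.

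Library totals were 1045482 counts for the control, 966943 for 3 min plasma and 615645 for 5 min plasma. A single count was therefore worth 0.956, 1.03 and 1.62 CPM, and the floor of 3 counts that a value of 0 allows was 2.87, 3.10 and 4.87 CPM. Of the listed miRNAs, 965 had a count in some library and 1623 had none in these 3. A mean of at least 20 counts over the 3 libraries was required for a comparison, which 231 miRNAs met; the other 2357 held 0.169% to 0.295% of each library.

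Scaling used the TMM method of edgeR 4.0.16 in R 4.3.3, computed over the 231 miRNAs with all 3 libraries together. The TMM factors were 1.000, 0.991 and 1.008. Computing them after the filter follows usual edgeR practice; the plan fixed TMM over the 3 libraries but not the set of miRNAs, so this set was chosen after the data were seen, and TMM over all listed miRNAs is given as an alternative. For each miRNA the scaled ratio of a pair of libraries was taken with an exact (Clopper-Pearson) 95% interval from the binomial split of its counts between them. Intervals and floors cover counting error only. With 1 library per group there was no replicate, no significance test and no p-value, and each ratio compares libraries, not conditions. The size rule was a ratio of at least 2-fold. Other code ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

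Before the data were examined, 22 miRNA lists, the comparisons, the size rule and the rule for named miRNAs were fixed. The lists were let-7, miR-17 to miR-92 with paralogs, p53-linked, miR-15/16, miR-29, miR-30, miR-23/27/24, miR-181, miR-10/99/125, redox-linked, melanocyte and melanoma, miR-506 to miR-514, the imprinted chromosome 14 cluster, non-canonical, entries overlapping other RNAs, and markers of epithelial, blood, muscle, liver, endothelial, fibroblast and neural cells. For each list with at least 3 measured members, the median log2 ratio was ranked among 10000 random lists of the same size matched on mean abundance. That percentile describes these libraries and is not a test. Members at least 1.5-fold from control were counted.

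Named miRNAs were the 10 most abundant in the control; for each comparison, the 10 higher and 10 lower ones whose counting interval lay farthest from 1, if at least 1.5-fold; 2 to 4 measured members per list with the largest such bound; and up to 5 per direction that were at least 2-fold from control at both exposures. Paralogs of near-identical sequence were to be given as uncertain. A few further miRNAs were named after their values were seen.

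Both exposures share the control library, so their agreement was set beside 1000 simulated sets of unchanged libraries, with counting error alone and with an assumed CV of 0.2 between libraries. The ratio step was tested on simulated counts for 5 min plasma against control, with 200 miRNAs given known folds before the filter. With counting error alone, the interval held the true value for 95.8% of 143 unchanged miRNAs and none reached 2-fold; all 30 miRNAs with a true 4-fold difference reached 2-fold, as did 54.5% of the 33 with a true 2-fold difference. With the assumed CV of 0.2, the interval held the true value for 51.8% of 143 unchanged miRNAs and 4.20% of them reached 2-fold. The counting intervals are thus too narrow for any spread between cultures.

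Hairpin positions, host genes and hairpin GC content came from the GENCODE 29 annotation on GRCh38, matched by miRNA name, which gave a position for all 231 miRNAs. The count tables hold no coordinates, so no builds were mixed. Host genes were taken on the hairpin's own strand from basic transcripts. Alternatives were scaling by the library total, by DESeq2 1.42.0 size factors, by the total without the 10 most abundant miRNAs and by TMM over all listed miRNAs; no filter, a mean of at least 5 and of at least 100 counts; a size rule that also requires the interval to exclude no difference; counts summed over families; libraries thinned to the smallest total; and the comparisons without entries overlapping other RNAs. The TMM alternative, the thinning and the removal of those entries were added after the data were seen. DESeq2 size factors were computed over all listed miRNAs, without the count filter.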

Results

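The series asked how a nonthermal plasma jet acts on the growth of melanoma cells, and profiled mature miRNAs in SK-MEL-2 cells that were untreated, exposed for 3 min or exposed for 5 min. Each group was 1 library, so no ratio below has a replicate check, and the given intervals are exact 95% counting intervals. Depth was 1045482 counts in the control, 966943 after 3 min and 615645 after 5 min of plasma. All positions are on GRCh38.

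Shares of the 10 most abundant miRNAs in the control were as follows. miR-21-5p, an oncogenic miRNA abundant in many tumours (MIR21, chromosome 17, 59841266 to 59841337, in an intron of VMP1), took 33.9% of the control counts (exact 95% interval 33.8 to 33.9), 34.1% after 3 min (33.99 to 34.18) and 33.97% after 5 min (33.85 to 34.08). let-7i-5p took 10.7%, 10.1% and 9.49% in that order, and let-7f-5p took 6.40%, 6.10% and 6.69%. miR-125b-5p made up 4.12%, 4.17% and 3.86%, and miR-27b-3p 3.47%, 3.52% and 3.92%. The shares of miR-99a-5p were 3.29%, 2.90% and 2.63%, those of let-7g-5p 2.63%, 2.77% and 2.75%, and those of let-7c-5p 2.27%, 2.07% and 1.86%. miR-221-3p, which represses the cell-cycle inhibitor CDKN1B, took 2.21% of control counts (2.18 to 2.24), 3.08% after 3 min (3.04 to 3.11) and 3.31% after 5 min (3.27 to 3.36). miR-26a-5p held 1.89%, 1.91% and 1.76%. The 10 leading miRNAs of each library together took 70.8%, 70.7% and 70.5%.

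The comparison of 3 min plasma with control asked what the shorter exposure left on Day 2. miR-539-3p, a member of the imprinted miRNA cluster on chromosome 14 (MIR539, 101047321 to 101047398, in an intron of MIR381HG), was 8.59-fold higher (5.60 to 13.7), with 189 counts against 24. miR-3176 (chromosome 16, 543277 to 543366, in an intron of CAPN15) was 10.1-fold higher (3.63 to 39.0), from 37 counts against 4. miR-1261 (chromosome 11, 90869121 to 90869202, no host gene on its strand) was 2.38-fold lower (2.13 to 2.66), with 446 counts against 1159. Most miRNAs lay close to control: 224 of 231 were within 2-fold, 5 were at least 2-fold higher and 2 at least 2-fold lower.

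Beside miR-539-3p and miR-3176, the 2-fold higher miRNAs were miR-4497 at 3.41-fold (1.49 to 8.75), miR-3916 at 2.49-fold (1.69 to 3.73) and miR-215-5p at 2.32-fold, whose interval of 0.948 to 6.21 included 1. The other 2-fold lower miRNA was miR-148a-3p, 2.32-fold lower (1.29 to 4.34) on 17 counts against 43. Between 1.5-fold and 2-fold, miR-4791 was 1.99-fold higher (1.68 to 2.37), miR-1246 1.76-fold (1.29 to 2.42), miR-34c-5p 1.76-fold (1.26 to 2.48), miR-4443 1.74-fold (1.26 to 2.42), miR-708-5p 1.72-fold (1.03 to 2.93) and miR-4792 1.69-fold (1.31 to 2.20). On the lower side were miR-1237-5p at 2.00-fold (1.26 to 3.24), just short of the size rule, miR-424-5p at 1.95-fold (1.18 to 3.31), miR-4454 at 1.78-fold (1.26 to 2.54), miR-6765-3p at 1.73-fold (1.12 to 2.70), miR-1260a at 1.62-fold (1.10 to 2.41) and miR-340-3p at 1.53-fold (1.31 to 1.79). At 1.5-fold, 16 miRNAs were higher and 12 lower. None of the 58 miRNAs with a mean of at least 1000 counts reached 1.5-fold at this exposure. Scaling by DESeq2 size factors gave 5 higher and 4 lower at 2-fold, as did TMM over all listed miRNAs.

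The comparison of 5 min plasma with control covered the longer exposure. miR-1246, an annotated miRNA whose hairpin (chromosome 2, 176600980 to 176601052) shares 19 bases with an annotated U2 small nuclear RNA, was 16.4-fold higher (12.7 to 21.3), with 660 counts against 68. The p53-linked miR-215-5p, miR-194-5p, miR-34c-5p and miR-192-5p were 8.85-fold, 2.63-fold, 2.57-fold and 2.17-fold higher. miR-125b-1-3p, the minor arm of MIR125B1 (chromosome 11, 122099757 to 122099844, in an intron of MIR100HG), was 2.14-fold lower (1.99 to 2.30), with 980 counts against 3530. At 2-fold, 22 miRNAs were higher, 8 were lower and 201 were neither.

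Of the miRNAs farthest above control, miR-3176 was 29.9-fold higher (11.2 to 113) on 71 counts against 4, miR-4497 (chromosome 12, 109833348 to 109833436) 21.3-fold (10.4 to 50.6) on 101 against 8, and miR-7704 (chromosome 2, 176188843 to 176188901, in an exon of HOXD1) 19.0-fold (8.81 to 48.8) on 79 against 7. miR-539-3p was 10.6-fold higher (6.86 to 17.1), miR-4792 (chromosome 3, 24521362 to 24521435) 6.32-fold (5.05 to 7.96) and miR-3916 4.75-fold (3.27 to 7.04). miR-4791 was 3.10-fold higher (2.61 to 3.68). miR-589-5p (chromosome 7, 5495819 to 5495917, in an intron of FBXL18) was 3.05-fold higher (2.61 to 3.57), with 458 counts against 253.

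On the lower side, miR-23b-5p was 2.75-fold below control (1.53 to 5.32) on 14 counts against 65, miR-1260a 2.65-fold (1.55 to 4.79), miR-301a-5p 2.505-fold (1.88 to 3.39) and miR-1261 2.11-fold (1.86 to 2.39). miR-340-3p was 1.98-fold lower (1.62 to 2.42), let-7a-3p 1.89-fold (1.62 to 2.22), miR-328-3p 1.80-fold (1.63 to 1.99) and miR-27a-5p 1.58-fold (1.43 to 1.75). miR-7-5p, a repressor of EGFR, was 1.56-fold lower (1.51 to 1.61), with 5489 counts against 14408. Its hairpin MIR7-2 on chromosome 15 lies antisense to MIR3529, whose miR-3529-3p had 14868 counts in the control and 8019 after 5 min, so the pair can share reads if strand was ignored, although miR-3529-3p had a 5 min log2 ratio of -0.14 (-0.18 to -0.10) against -0.64 (-0.68 to -0.59). miR-3529-3p was named after its values were seen.

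**Figure D1:**
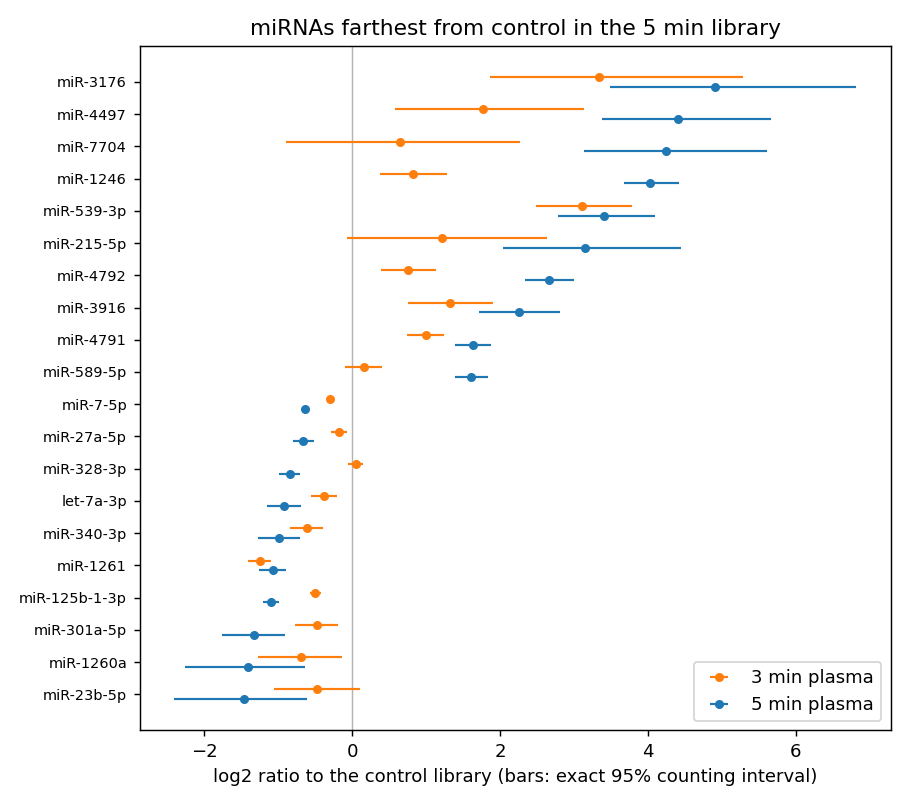
The 10 higher and 10 lower miRNAs whose counting interval lay farthest from 1 in the 5 min comparison. Points are log2 ratios to the control library after 3 min (orange) and 5 min (blue) of plasma, with exact 95% counting intervals as bars, 1 library per group. miR-1246 stood at 0.82 after 3 min and 4.03 after 5 min, and miR-1261 at -1.25 and -1.08.

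At 1.5-fold, 40 miRNAs were higher after 5 min and 27 lower. The spread of log2 ratios over the 231 miRNAs was 0.88 (SD), against 0.48 after 3 min. Scaling set the balance of directions. The library total gave 22 higher and 7 lower at 2-fold, and the total without the 10 most abundant miRNAs 22 and 8. DESeq2 size factors over the filtered miRNAs were not computed. Over all listed miRNAs, so with those below the filter, DESeq2 size factors gave 18 and 17, and TMM 18 and 16. These shifted the median log2 ratio, 0.05 in the main scaling, by as much as -0.21 after 5 min and -0.07 after 3 min, so small positive ratios could change sign with the scaling. Among the 58 miRNAs with a mean of at least 1000 counts, miR-125b-1-3p was at least 2-fold lower after 5 min and none was 2-fold higher.

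Among the lists, the p53-linked miRNAs stood high. All 6 measured members had positive log2 ratios after 5 min in the main scaling, 4 of them at least 1.5-fold higher in each of the 5 scalings, and the list's median of 1.24 was at percentile 99.9 of matched random lists. miR-215-5p (chromosome 1, 220117853 to 220117962) had 8, 17 and 42 counts in control, 3 min and 5 min, an interval of 4.10 to 21.8-fold for the last. miR-192-5p (chromosome 11, 64891137 to 64891246, in an exon of MIR194-2HG), a near-identical sequence, had 73, 75 and 94 (1.58 to 2.99-fold). miR-194-5p had 34, 38 and 53 counts (1.68 to 4.17-fold), and miR-34c-5p (chromosome 11, 111513439 to 111513515) had 59, 95 and 90 (1.83 to 3.63-fold). The hairpins of miR-194-5p lie beside MIR215 (MIR194-1, chromosome 1, 220118157 to 220118241) and beside MIR192 (MIR194-2, chromosome 11, 64891355 to 64891439). miR-192-5p, miR-194-5p and miR-215-5p are therefore not independent members, which the matched random lists do not take into account. The remaining members were miR-107 at a log2 ratio of 0.22 (-0.28 to 0.71) and miR-143-3p at 0.23 (-0.28 to 0.72). miR-34a-5p, the best-known p53 target of the list, was below the count filter with 17, 21 and 18 counts; it and miR-107 were named after their values were seen. After 3 min the list's median was 0.38, at percentile 96.7, with 2 members at least 1.5-fold higher. Markers of epithelial cells, which also express miR-192-5p, miR-194-5p and miR-215-5p in some organs, summed to 16, 29 and 44 counts, a log2 ratio of 2.21 (1.36 to 3.14) after 5 min and 0.98 (0.06 to 1.96) after 3 min. These sums rested mostly on miR-200b-3p (6, 13 and 20 counts) and miR-200c-3p (6, 8 and 17), both named after their values were seen.

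Entries of the list overlapping other RNAs split after 5 min: 5 of the 8 measured were at least 1.5-fold higher and 3 at least 1.5-fold lower. Beside miR-1246, miR-1290 was 3.18-fold higher (1.93 to 5.32), miR-6087 2.90-fold (2.42 to 3.48) and miR-7641 2.87-fold (2.27 to 3.63); miR-663a, the fifth, was chosen after its values were seen and had a log2 ratio of 1.505 (0.904 to 2.124). The hairpins of miR-7641 share 49 and 53 bases with annotated 5S ribosomal RNA pseudogenes. miR-1260a, miR-1260b and miR-4454, assigned beforehand to transfer RNA with no match in the annotation used, had log2 ratios of -1.41 (-2.26 to -0.64), -0.79 (-1.54 to -0.09) and -0.63 (-1.21 to -0.08); miR-1260b was named after its values were seen. The list's median of 1.51 was at percentile 99.8; after 3 min it was 0.21, at percentile 76.6, with 1 member higher and 2 lower.

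The miR-29 family, which represses collagen and other matrix mRNAs, had a median of 0.69 after 5 min (percentile 91.7) and 0.32 after 3 min (percentile 86.5). miR-29a-3p was 1.62-fold higher after 5 min (1.57 to 1.66), with 11185 counts against 11660 in the deeper control. miR-29c-3p was 1.88-fold higher (1.16 to 3.05) and miR-29b-3p 1.19-fold (1.01 to 1.42); under other scalings as few as 1 member reached 1.5-fold. The miR-181 list stood at 0.25 (percentile 80.4), with miR-181a-5p 1.54-fold higher (1.37 to 1.74), miR-181b-5p 1.19-fold (1.06 to 1.34) and miR-181d-5p 1.18-fold (1.01 to 1.38), near-identical paralogs of which 0 reached 1.5-fold under another scaling; after 3 min its median was 0.14 (percentile 80.8). Non-canonical miRNAs are made without a step of the usual processing. Those listed had a median of 0.39 at both exposures (percentiles 83.0 after 5 min and 93.0 after 3 min). Of these, miR-320a was 1.41-fold higher after 5 min (1.15 to 1.72), miR-320c 1.63-fold (0.963 to 2.76), miR-320b 1.21-fold (0.911 to 1.60) and miR-484 1.22-fold (0.910 to 1.63).

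Below control stood the list of miR-10, miR-99 and miR-125 members, with a median of -0.25 after 5 min (percentile 10.0) and -0.09 after 3 min (percentile 6.95). After 5 min miR-99b-5p was 1.49-fold lower (1.42 to 1.57), miR-99a-5p 1.26-fold (1.24 to 1.28) and miR-10a-5p 1.21-fold (1.15 to 1.28), while miR-125a-5p was 1.23-fold higher (1.18 to 1.27). Of the let-7 list, which holds 5p arms and no 3p arm such as let-7a-3p, and whose members repress RAS and HMGA2, no member reached 1.5-fold. The let-7 median was -0.12 after 5 min (percentile 18.6) and 0.01 after 3 min (percentile 42.7, sign dependent on scaling). After 5 min let-7c-5p was 1.23-fold lower (1.2 to 1.25), let-7e-5p 1.22-fold (1.13 to 1.31), let-7b-5p 1.204-fold (1.16 to 1.24) and let-7i-5p 1.13-fold (1.12 to 1.14); let-7d-5p had a log2 ratio of 0.09 (0.03 to 0.15), whose sign changed with scaling.

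Melanocyte and melanoma miRNAs went both ways, with a median of -0.03 after 5 min (percentile 58.7) and 0.08 after 3 min (percentile 68.3). miR-221-3p was 1.49-fold higher after 5 min (1.46 to 1.51) and 1.40-fold after 3 min (1.38 to 1.43). miR-222-3p, from the same primary transcript (chromosome X, 45747015 to 45747124), was 1.30-fold higher after 3 min (1.25 to 1.36) and 1.27-fold lower after 5 min (1.205 to 1.333). miR-146a-5p, an NF-kB target, was 1.46-fold higher after 5 min (1.34 to 1.58). miR-148a-3p had a log2 ratio of -0.03 (-0.80 to 0.71) after 5 min. In the redox-linked list, miR-7-5p was the 1 member beyond 1.5-fold; miR-21-5p, miR-27a-3p and miR-28-5p stood at -0.01 (-0.01 to 0.00), 0.05 (0.01 to 0.08) and -0.14 (-0.52 to 0.23) on the log2 scale, and the signs of miR-21-5p and miR-27a-3p changed with scaling. The list's median was -0.02 after 5 min (percentile 34.9) and 0.02 after 3 min (percentile 36.3, sign dependent on scaling).

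Medians of 4 further lists after 5 min lay near 0 and changed sign with the scaling: miR-17 to miR-92 at 0.02 (percentile 49.7), miR-15/16 at 0.05 (percentile 48.0), miR-30 at 0.15 (percentile 84.0) and miR-23/27/24 at 0.05 (percentile 77.4). After 3 min these medians were 0.15 (percentile 88.1), -0.03 (percentile 20.03), 0.10 (percentile 79.3) and -0.01 (percentile 33.6). Members that stood apart after 5 min were miR-19b-3p, 1.69-fold higher (1.18 to 2.41), miR-20a-5p, 1.504-fold (1.34 to 1.69), and miR-17-5p, 1.25-fold (1.08 to 1.44), of the MYC-driven miR-17 cluster, while its most abundant member, miR-92a-3p, was 1.14-fold lower (1.07 to 1.22). miR-30b-5p was 1.61-fold higher (1.39 to 1.86), miR-30a-5p 1.30-fold (1.22 to 1.38), miR-16-5p 1.42-fold (1.22 to 1.64) and miR-23a-3p 1.28-fold (1.197 to 1.370). Under another scaling, 0 members of the miR-17 to miR-92 list and 0 of the miR-30 list reached 1.5-fold higher.

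Markers of other cell types ranged from 16885 control counts of the neural miR-9-5p to none. The fibroblast list had a median of 0.56 after 5 min (percentile 97.6), with miR-199b-5p 1.63-fold higher (1.12 to 2.37), miR-199a-5p 1.56-fold (1.19 to 2.04) and miR-199a-3p 1.39-fold (1.33 to 1.46); after 3 min it was 0.23 (percentile 90.9). The separate values of these near-identical paralogs are uncertain. miR-199a-3p and miR-199a-5p are also arms of the same hairpins. The miR-199 members are therefore not independent, which the matched random lists do not take into account. Under another scaling the 5 min median was 0.35 and the members at 1.5-fold went from 2 to 0. Neural miRNAs had a median of -0.26 (percentile 7.74), with miR-128-3p and miR-129-5p each 1.52-fold lower (1.38 to 1.68 and 1.21 to 1.94); after 3 min it was 0.10 (percentile 67.8). The far more abundant miR-9-5p had a log2 ratio of 0.15 (0.12 to 0.19) after 5 min and miR-9-3p 0.075 (-0.38 to 0.52), both with signs that changed with scaling, and the summed neural counts had 0.10 (0.06 to 0.13). The muscle list summed to 15, 20 and 30 counts, a log2 ratio of 1.75 (0.81 to 2.75) after 5 min. The largest part came from miR-1-3p (0, 3 and 15 counts). miR-499a-5p had 14, 14 and 13 counts, which scaled to the shallower 5 min library also lies above control. Both miRNAs were named after their values were seen. The blood list summed to 17, 21 and 14, a log2 ratio of 0.47 (-0.66 to 1.58). Liver miR-122-5p had a log2 ratio of 0.17 (-0.27 to 0.60) and endothelial miR-126-3p 0.25 (-0.00 to 0.50). The miR-506 to miR-514 cluster of melanocytic cells had 4, 3 and 4 counts in all.

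**Figure D2:**
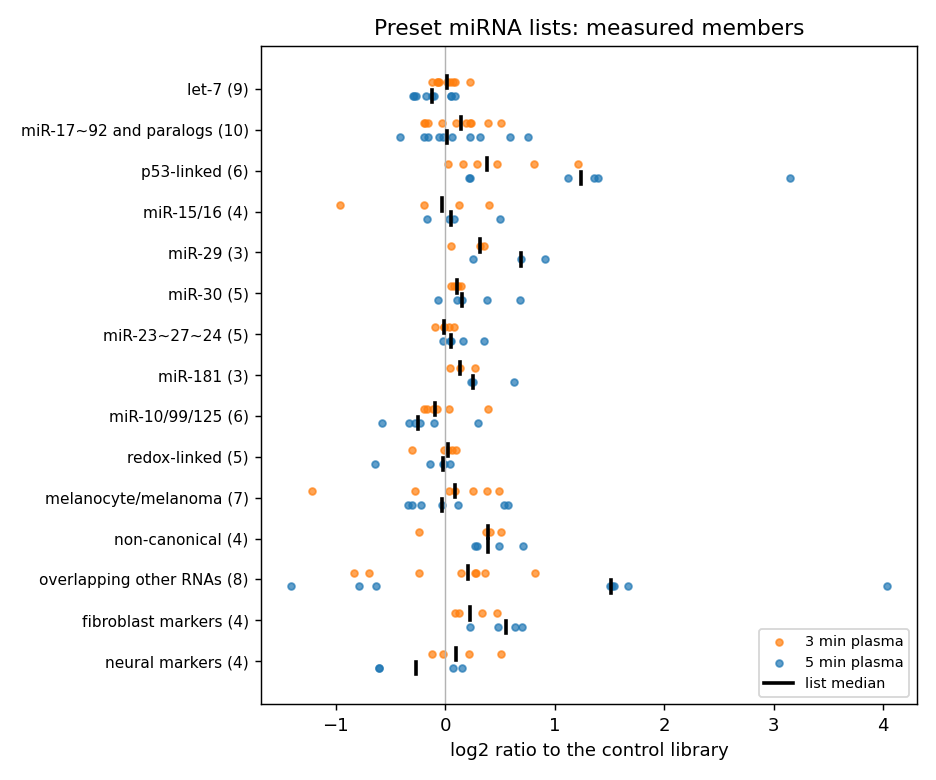
Measured members of the preset lists, as log2 ratios to the control library after 3 min (orange) and 5 min (blue) of plasma; black bars are list medians and the number of measured members is in parentheses. After 5 min the p53-linked median was 1.24 and that of entries overlapping other RNAs 1.51, while the let-7 median was -0.12.

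The comparison of 5 min with 3 min plasma asked whether the longer exposure differed from the shorter one. The control library did not enter these ratios themselves, but it did enter the TMM factors and the count filter. miR-7704 was 12.2-fold higher after 5 min (6.30 to 26.4), miR-1246 9.26-fold (7.56 to 11.4), miR-4497 6.24-fold (3.99 to 10.1) and miR-4792 3.74-fold (3.09 to 4.53). miR-215-5p was 3.81-fold higher (2.13 to 7.15), and miR-589-5p 2.74-fold (2.35 to 3.21). miR-539-3p was 1.23-fold higher, with an interval of 0.989 to 1.54 that included 1. At 2-fold, 15 miRNAs were higher after 5 min and 2 were lower.

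The lower pair was miR-4510, 2.51-fold (1.13 to 6.32), and miR-139-5p, 2.08-fold (1.12 to 4.11). Among more abundant miRNAs, miR-328-3p was 1.86-fold lower (1.69 to 2.06), miR-128-3p 1.77-fold (1.60 to 1.95), miR-222-3p 1.65-fold (1.57 to 1.74) and its minor arm miR-222-5p 1.79-fold (1.35 to 2.40). miR-301a-5p was 1.80-fold lower (1.33 to 2.47), miR-125b-1-3p 1.51-fold (1.40 to 1.63), miR-129-5p 1.503-fold (1.18 to 1.92) and miR-3184-5p, whose hairpin is antisense to MIR423, 1.5-fold (1.29 to 1.74). Other miRNAs farthest above were miR-6087 at 2.62-fold (2.19 to 3.14) and miR-7641 at 2.23-fold (1.78 to 2.79). miR-1237-5p was 3.09-fold higher (1.93 to 5.05) and miR-3176 2.96-fold (1.96 to 4.54). DESeq2 size factors gave 14 higher and 5 lower at 2-fold, and TMM over all listed miRNAs 14 and 4.

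The 2 exposures shared part of their pattern against the common control. miR-539-3p, miR-3176, miR-3916, miR-4497 and miR-215-5p were at least 2-fold higher at both, and miR-1261 at least 2-fold lower at both. All 5 miRNAs at least 2-fold higher after 3 min were thus also so after 5 min, where 0.476 would be shared by independent lists. Simulated unchanged libraries shared 0.0540 on average with counting error alone, and 1.06 with an assumed CV of 0.2, where the highest simulated number was also 5. Of the 231 miRNAs, 171 had log2 ratios of the same sign (74.0%). The simulated libraries gave means of 147 with counting error alone and 153 with the assumed CV, and highest numbers of 171 and 174. The observed number thus lay within reach of unchanged libraries that share a control. Of the 171, 131 lay farther from 0 after 5 min. No simulated value was made for that number, and the shallower 5 min library carries more counting error. Across miRNAs, which are not independent replicates, Pearson's r was 0.729 and Spearman's rho 0.648. Simulated unchanged libraries with counting error alone gave a mean Pearson r of 0.421, and 0.477 with an assumed CV of 0.2, with highest values of 0.642 and 0.619. The covariance was 0.307, against means of 0.0228 and 0.108 in those simulations, a difference of 0.284 and 0.1997, and highest values of 0.0497 and 0.163. The single control library could not be split, so part of the excess may come from it: a CV of 38.3% in that library, added to counting error, would give the observed covariance. Without the 10 miRNAs with the largest ratios, Pearson's r was 0.531 and the covariance 0.0956. Simulated libraries trimmed in the same way gave means of 0.295 and 0.0108 with counting error alone, and highest values of 0.524 and 0.0230. With the assumed CV they gave 0.388 and 0.0716, and highest values of 0.548 and 0.118, so the trimmed agreement lay within that simulated range.

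**Figure D3:**
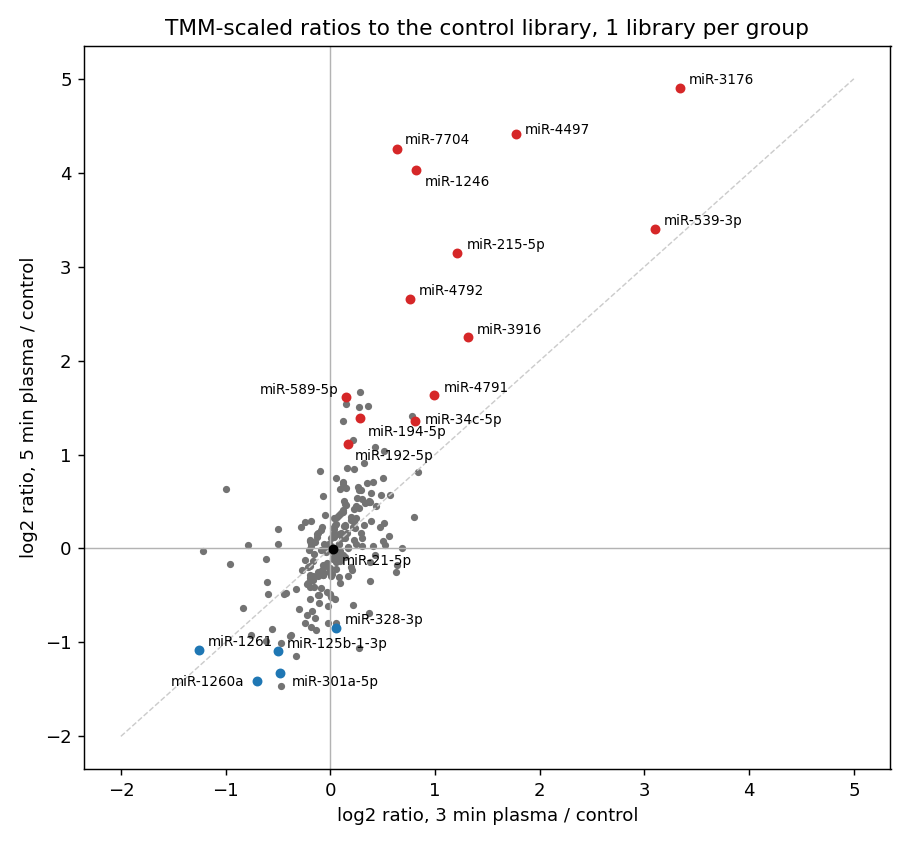
Log2 ratio to the control library after 3 min (horizontal) and 5 min (vertical) of plasma for 231 miRNAs, 1 library per group; the dashed line marks equal ratios. Labelled points are red where the 5 min ratio was at least 1.5-fold above control, blue where at least 1.5-fold below, and miR-21-5p is black. miR-3176 and miR-539-3p lie far from control at both exposures, while miR-1246 and miR-7704 are at 4.03 and 4.25 after 5 min against 0.82 and 0.64 after 3 min.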

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

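All tests of explanations in this part were chosen after the results were seen, as were the miRNAs named from below the count filter, among epithelial markers and among antisense partners. 8 named miRNAs stood on opposite sides of control at the 2 exposures with counting intervals that excluded no difference, a contrast that was not tested against any spread between cultures. In 4 of them the opposite signs held in all 5 scalings: the log2 ratio of 5 min to 3 min was 1.63 for miR-1237-5p, -0.82 for miR-128-3p, -0.72 for miR-222-3p and -0.39 for miR-92a-3p. In the other 4 a sign depended on the scaling: the ratio was 0.11 for let-7f-5p, -0.14 for miR-125b-5p, -0.12 for miR-30d-5p and 0.28 for miR-9-5p.

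Outside the comparisons, 14 of the 2357 miRNAs below the count filter had a 5 min ratio whose lower counting bound exceeded 2-fold, and none did after 3 min. Only higher ratios were screened, so lower ones were not looked for. Of those with counts in the control, miR-4508 had a log2 ratio of 3.56 (1.82 to 5.95) on 21 counts against 3. miR-718 and miR-4662a-5p each had 2.84 (1.70 to 4.16) on 34 against 8, and miR-5187-5p had 2.84 (1.22 to 4.87) on 17 against 4. miR-182-5p, of a cluster raised in melanoma, had 2.66 (1.01 to 4.71) on 15 against 4. The epithelial miR-200b-3p had 2.49 (1.12 to 4.09) on 20 against 6, miR-6807-3p 2.40 (1.203 to 3.755) and miR-1244 2.28 (1.06 to 3.65). With 0 counts in the control, the log2 ratio against the floor of 3 counts in that library was at least 3.25 for miR-4485-3p, 3.07 for the muscle marker miR-1-3p, 2.87 for miR-3195, 2.49 for miR-3131, and 1.98 for miR-6126 and for miR-6809-3p. These take the 5 min count as exact; with its counting error, the exact lower bounds were 2.80, 2.595, 2.36, 1.92 and 1.28 in that order, the last for both. Together the miRNAs below the filter held 0.295% of the 5 min counts (exact 95% interval 0.282 to 0.309) against 0.169% of control counts (0.161 to 0.177).

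Of the 6 measured p53-linked miRNAs, 4 were at least 1.5-fold higher in the 5 min library, while the intervals of miR-107 and miR-143-3p included no difference. The higher miR-192-5p, miR-194-5p and miR-215-5p come from neighbouring hairpins and are not independent. A mere exchange of reads between the near-identical miR-192-5p and miR-215-5p is argued against as the cause. Their summed counts had a log2 ratio of 1.5 (1.09 to 1.92). The sum cannot tell which of them was higher, so reads of miR-192-5p counted as miR-215-5p, or the reverse, stay possible. Whether scarce miRNAs rose in general could be asked only above the count filter. There, the 82 other measured miRNAs within the list's range of mean counts (22.3 to 84) had a median of 0.035. It lay below the list's median of 1.24 by 1.21 (log2), little more than their SD of 1.09. Rarer miRNAs, which the filter kept out of this test, did go up, by 1.74-fold in sum. miR-215-5p, with 8 control counts, was as scarce in the control as some of those. A general rise of scarce miRNAs thus stays open. RNA of an epithelial source stays open. The epithelial list summed to a log2 ratio of 2.21 (1.36 to 3.14), on 44 counts against 16. Most came from miR-200b-3p (20 counts against 6) and miR-200c-3p (17 against 6). miR-203a-3p had 4 against 1, miR-200a-3p 2 against 2, miR-141-3p 1 against 1, and miR-429 and miR-205-5p 0 in both. Other scarce lists rose in sum too, muscle by 1.75 and chromosome 14 by 1.39 (log2), while the blood interval (-0.66 to 1.58) included no difference. The epithelial sum is thus not particular to an epithelial source. No other list holds these 7 markers except miR-200a-3p and miR-141-3p, which are also in the redox-linked list. An effect of the plasma exposure was not separable from a difference between cultures and stays open as well.

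Entries overlapping U2 or ribosomal RNA (miR-1246, miR-1290, miR-663a, miR-6087 and miR-7641) were higher in the 5 min library. Only for miR-1246 and miR-7641 did the annotation hold a matching transcript, so the others belong here by prior assignment. More fragments of all structural RNAs are argued against so far as miR-1260a, miR-1260b and miR-4454 come from transfer RNA, since they had a summed log2 ratio of -0.88 (-1.27 to -0.51). Their link to transfer RNA is also a prior assignment, with no matching transcript in the annotation. GC content is argued against for miR-1246, miR-1290 and miR-7641, whose median excess over the 20 miRNAs nearest in hairpin GC was 1.65 (log2; SD of such neighbours 0.59), while for miR-663a and miR-6087 it cannot be told apart, since their excess of 1.5 is below the neighbours' SD of 1.81. More fragments of U2, ribosomal and mitochondrial ribosomal RNA may be present: miR-4485-3p, which shares 24 bases with mitochondrial MT-RNR2, had 17 counts after 5 min, 1 after 3 min and 0 in the control, a log2 ratio of 5.78 (3.10 to 11.2) to the other libraries together, and whether breakdown of RNA in the cells or in handling would give this is open.

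Counts of miRNAs with antisense hairpins were close to those of their partners. In the control library 6 of 9 antisense partners lay within 2-fold of each other, against a median of 1 and a highest value of 6 in 10000 random re-pairings, as counting that ignored strand would give. miR-374b-5p and miR-374c-3p (1045 and 972) are an example, while miR-24-3p and miR-3074-5p (16037 and 1324) differ. Against reads shared in full, 2 of the 6 close pairs parted after 5 min with intervals that did not overlap. miR-3529-3p and miR-7-5p, with 14868 and 14408 control counts, had log2 ratios of -0.14 (-0.18 to -0.10) and -0.64 (-0.68 to -0.59), and miR-3065-5p and miR-338-3p had 1.08 (0.50 to 1.67) and -0.49 (-1.28 to 0.26). Whether strand was ignored stays open. No biological explanation was tested for this pattern.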

How the results depend on the processing

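The scaling by TMM over all listed miRNAs, the thinning, and the removals of entries overlapping other RNAs and of the 10 largest ratios were chosen after seeing the data. No paired analysis was possible because there is 1 library per group, and leaving out a replicate was not possible for the same reason. No pseudocount entered the filtered comparisons, so none was varied there. Among these alternatives, 0.5 was added only where no filter was used. Counts of 2-fold miRNAs, higher then lower, are given for 3 min, 5 min and 5 against 3 min. The main counts were 5 and 2, 22 and 8, and 15 and 2. With no filter and 0.5 added they were 209 and 171, 337 and 56, and 308 and 56; at a mean of at least 5 counts, 21 and 14, 64 and 23, and 59 and 17; at a mean of at least 100, 1 and 1, 7 and 3, and 5 and 0. These differ by construction in the number of miRNAs compared. DESeq2 size factors gave 4, 17 and 5 lower and TMM over all listed miRNAs 4, 16 and 4 lower. Both were computed with the miRNAs below the count filter. DESeq2 size factors were not computed without them, so the cause was not tested for that method. All 18 higher miRNAs of either scaling after 5 min were among the main 22, and all 8 lower ones of the main scaling stayed lower in both. Without the preset list of entries overlapping other RNAs, 17 higher and 7 lower remained after 5 min. Only hairpins of that list were searched for stretches shared with other RNAs, so the remaining miRNAs may carry such fragments too. Summing families left 1 lower after 3 min, and thinning gave 9 and 4 after 3 min. Pearson's r of the exposures was 0.601 at a mean of at least 5 counts and 0.531 without the 10 largest ratios, against 0.729. No count moved by over 1.5 times when scaled by library total. Of 273 values of 91 named miRNAs, 93 left their counting interval under DESeq2 size factors, 84 under TMM over all listed miRNAs, 53 when summed over families, 8 under the library total and 0 when thinned; none that was at least 1.5-fold changed sign. Depth limits the 5 min library most, where 1 count is 1.62 CPM.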

Other observations

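All tests in this part were chosen after the results were seen, as were the hairpin arms named. The difference between the arms of a hairpin does not depend on scaling. It compares products of 1 precursor only where neither arm also comes from another hairpin, as for the arms of miR-23b, miR-27b, miR-335 and let-7c below. Even there, reads can be shared with near-identical paralogs, as for let-7c-5p, and for miR-23b-3p and miR-27b-3p with miR-23a-3p and miR-27a-3p. miR-125b-5p, miR-29b-3p, miR-16-5p and let-7a-5p come from several hairpins. After 5 min several minor arms stood far below control while the major arm did not. miR-23b-5p had a log2 ratio of -1.46 and miR-23b-3p 0.05, miR-125b-1-3p -1.10 and miR-125b-5p -0.11, miR-29b-1-5p -1.14 and miR-29b-3p 0.26, miR-16-1-3p -0.87 and miR-16-5p 0.50, and miR-27b-5p -0.93 and miR-27b-3p 0.16. let-7a-3p and let-7a-5p stood at -0.92 and -0.12. In the other direction, miR-335-5p had 0.86 and miR-335-3p -0.22, and let-7c-3p had 0.56 and let-7c-5p -0.30.

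One hypothesis is that minor arms were lost across hairpins after 5 min. Of 59 hairpins with both arms measured, the minor arm had the lower ratio in 33, or 55.9% (exact 95% interval 42.4 to 68.8), with a median difference of -0.03 (log2), which argues against a loss across hairpins. Without the 14 hairpins that have an arm of the same name also made from another hairpin it was 23 of 45, or 51.1% (35.8 to 66.3), with a median difference of -0.01. Near-identical paralogs under another name, such as MIR199B, were kept. So were both hairpins of antisense pairs, such as MIR3184 and MIR423. The hairpins are thus not all independent, which the exact intervals do not take into account. Among these 45, 2 minor arms were at least 2-fold lower than their major arm and 3 higher; among all 59 it was 4 and 3. After 3 min the minor arm was lower in 36 of the 59, with a median difference of -0.10.

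The number of miRNAs detected went up while depth went down. Detected were 639 miRNAs in the control library and 708 after 5 min. At 615645 counts per library, the means over 100 draws were 549.87 (SD 6.69) for the control and 580.93 (SD 6.99) after 3 min. Counts in miRNAs below the filter, scaled as the rest, were 1.74-fold those of control after 5 min (1.63 to 1.86) and 1.08-fold after 3 min (1.01 to 1.15).

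The imprinted chromosome 14 list summed to 56, 90 and 87 counts in control, 3 min and 5 min, a log2 ratio of 0.81 (0.31 to 1.32) after 3 min and 1.39 (0.89 to 1.90) after 5 min. Below the count filter, miR-381-3p (9, 5 and 22 counts) and miR-136-5p (8, 16 and 18), named after their values were seen, contributed more to the 5 min difference than any other member. Its single measured member, miR-337-3p, stood at 0.68 (0.00 to 1.38) and 0.00 (-0.90 to 0.86). miR-539-3p, of the same region but not in the list, had 24, 189 and 151 counts.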
